A study of Homo sapiens with 24 samples.

How the data were processed

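RNA that came down with a GFP-tagged protein was sequenced (RNA immunoprecipitation sequencing) from HCT116 cells, a human colorectal carcinoma line. CRISPR knock-in had placed GFP on RUVBL1, an AAA+ ATPase, or on RPAP3, a scaffold of the R2TP chaperone complex that also holds RUVBL1 and RUVBL2. Each lysate was passed over GFP-Trap beads, here called GFP beads, or over agarose beads without the antibody fragment, here called uncoupled beads. Cells were untreated, given puromycin (100 µg/mL, 30 min), which releases nascent chains from ribosomes, or, in the RUVBL1 line, given the RUVBL1/2 ATPase inhibitor CB-6644 (0.5 µM, 16 h) alone or with puromycin.

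The authors deposited 1 table of read counts per gene over all 24 libraries, whole numbers that had not been normalized. Per the submitters' processing notes the tools were bcl2fastq 2.20.0.422, FastQC 0.11.9, MultiQC 1.12, TopHat2 2.1.1 and featureCounts 2.0.3, with genome build hg38. Libraries were made with a stranded SMART-Seq kit, per the labels' protocols. The strand setting, the treatment of reads with several placements and the annotation release were not given in the sources used here. Reads of near-identical copies, of overlapping genes and of antisense pairs could therefore have been split or merged, and no molecular identifiers separated PCR copies. The table had 28307 genes, of which 27790 carried a gene ID. Of those IDs 27757 were found in the NCBI gene table for GRCh38.p14, from which positions and biotypes were taken. Another 517 genes had no ID, and 237 of them were named through the table. Transcript lengths and a genome sequence were not used here, so no check of GC content or length was made.

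Groups came from the labels: 12 groups of 2 libraries, 8 groups in the RUVBL1 line and 4 in the RPAP3 line. Total counts ranged from 9019665 to 33051512 per library in the RUVBL1 line and from 30844089 to 50394245 in the RPAP3 line. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Counting intervals cover counting error only.

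Each comparison was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust dispersion) with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The 16 RUVBL1 libraries were fitted together (15976 genes, common biological coefficient of variation 0.263), the 8 RPAP3 libraries together (15202 genes, 0.142), and all 24 where a comparison spanned both lines (16695 genes, 0.229). Enrichment is the log2 ratio of GFP beads to uncoupled beads of the same treatment, 2 libraries against 2. It is given with a standard error derived from the test's F statistic. The variance behind that error was pooled over all libraries of the fit and moderated across genes. It is therefore not the spread of the libraries compared. A change in enrichment is the difference of 2 such ratios, tested as an interaction. Levels are CPM, counts scaled by depth and TMM factor, with the SD of 2 libraries. Positive values mean higher on GFP beads, or higher after the drug. Where an enrichment is said to rise or fall, the RNA was higher or lower on GFP beads than on uncoupled beads of that treatment. Such wording is no change with the drug.

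The tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule took RUVBL1, RUVBL2 and RPAP3 always. It also took the 10 called genes with the largest log2 change in each direction, among those with a mean of at least 5 CPM. That mean was not limited to the groups compared, so some genes so named lay below 5 CPM in them. Both GFP libraries had to lie on one side of both bead libraries in an enrichment. Up to 4 members of each list with the smallest p completed it. Genes named outside the rule are said to be so. Each of 24 gene lists was tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. The lists covered R2TP and prefoldin-like subunits, PIKK kinases with their TTT co-chaperone, the INO80, SRCAP and TIP60 complexes, RNA polymerase subunits and assembly factors, snoRNP proteins and their assembly factors, U5 and U4/U6 snRNP proteins, and the TSC complex. Further lists were HSP90 and HSP70 chaperones, the CCT chaperonin with prefoldin, the proteasome, eIF3, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, snoRNAs and scaRNAs, other structured or nuclear non-coding RNAs, replication-dependent histones, ER chaperones, ATF4 targets, p53 targets, immediate early genes, mitotic genes, very long cytosolic proteins, colon epithelial genes, and markers of blood, stromal and liver cells as a contamination check. The mitochondrially encoded list had 0 members in the table. Of 99 camera calls among 322 tests, 1 held when the correlation was estimated from the libraries, and 17 held in fry, which called 5 more.

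Overlaps of calls were tested with a one-sided Fisher's exact test over genes tested in both fits. That test takes genes as independent, which correlated genes are not, so its p-values are likely too small. No library was shared between the comparisons so overlapped. Alternatives were upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter or a filter at a mean of 50 counts, removal of the 10 most abundant genes, non-robust dispersion, the replicate number as a block over a line or within a treatment, an adjusted p under 0.01, an added log2 change of at least 1, other sets of libraries in the fit, GFP libraries compared directly, and each library left out in turn. When 1 library was left, it was assumed to vary like the other groups.

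The fit was tested on simulated counts with known changes in 100 genes per fold size. Changed genes were drawn only from those above a minimum expected count, and no library was made to stand apart from its group. The shares below therefore do not carry over to genes with few counts, such as many snoRNAs, or to groups with an outlying library. For the RUVBL1 untreated enrichment (15397 genes) 39% of genes changed 2-fold and 77% changed 4-fold were recovered, and 4.55% of 132 calls were unchanged genes. For the puromycin change in RUVBL1 enrichment these shares were 6% and 62%, with 4.17% of 72 calls unchanged. The RPAP3 untreated enrichment (14919 genes) gave 75% and 94%, with 5.37% of 205 calls unchanged, and the RPAP3 puromycin change gave 56% and 90%, with 7.30% of 178. Simulated bead comparisons with no change gave 0 calls in the RUVBL1 line and 1 in the RPAP3 line.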

Results

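The libraries measured which RNAs were recovered with GFP-tagged RUVBL1 or RPAP3 from HCT116 cells, over the RNA that stuck to uncoupled beads. The comparisons ask which mRNAs were bound by the chaperones while their proteins were being made, since puromycin releases nascent chains, and whether recovery needed the ATPase activity that CB-6644 blocks. Log2 counts of replicate pairs correlated at 0.932 to 0.984 across genes. Every pair differed by more than sampling noise, with a chi-square per degree of freedom of 13.5 to 99.8, so no libraries were merged for the tests. The first principal component held 24.4% of the variance in the RUVBL1 line and 48.2% in the RPAP3 line. Replicate 2 of the GFP beads after CB-6644 lay at 110.5 on that component and replicate 1 of the GFP beads after both drugs at 71.98, against a highest value of 11.7 for the other RUVBL1 libraries. Replicate 2 of the untreated RUVBL1 uncoupled beads lay at -89.4 on the next component and had 10974407 counts.

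In untreated cells RUVBL1 recovered mRNAs of subunits of spliceosomal, chromatin and polymerase complexes. PRPF8, the central protein of the U5 snRNP (chromosome 17, 1650629 to 1684867, hg38), was 6.44 ± 0.45 higher on GFP beads on the log2 scale, an 87.1-fold difference (adjusted p = 1e-08). Its raw counts were 518139 and 286975 on GFP beads against 6586 and 1281 on uncoupled beads. EP400, the ATPase of the TIP60 complex (chromosome 12, 131949942 to 132080460), was 6.07 ± 0.44 higher, and SRCAP, its relative in the SRCAP complex, 4.86 ± 0.40. POLR2A, POLR1A and POLR3A, the largest subunits of RNA polymerases II, I and III, were 4.47 ± 0.51, 3.90 ± 0.48 and 3.07 ± 0.42 higher. GOLGA4, a golgin of the trans-Golgi (chromosome 3, 37243271 to 37366879), stood at 3073 ± 539 CPM against 160.2 ± 48.4 CPM (SD, n = 2 each), a log2 difference of 4.26 ± 0.38. In all 146 genes were higher and 3 lower of 15976 tested. The lower ones were BPNT1 at -1.36 ± 0.31, H4C11 at -1.16 ± 0.25, whose near-identical histone copies make its count uncertain, and CD109 at -0.88 ± 0.21.

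By list, 4 of 30 INO80, SRCAP and TIP60 members rose with RUVBL1 (5 adjusted over the list alone), namely EP400, SRCAP, BRD8 at 3.19 ± 0.26 and INO80 at 1.87 ± 0.25. The list's camera adjusted p was 8.58e-05, and adjusted p = 0.488 with an estimated correlation. RNA polymerase subunits and assembly factors had 4 of 31 higher (6 over the list alone), the fourth being POLR2B at 3.57 ± 0.33, with camera adjusted p = 8.58e-05 and adjusted p = 0.538 with an estimated correlation. Among U5 and U4/U6 snRNP proteins 3 of 16 rose, PRPF8, EFTUD2 at 3.58 ± 0.69 and CD2BP2 at 0.88 ± 0.21 (3 over the list alone, camera adjusted p = 5.11e-05, adjusted p = 0.488 with an estimated correlation). SMG1, a PIKK kinase of nonsense-mediated decay, rose by 2.38 ± 0.30 as the one called member of 9 (2 higher and 1 lower over the list alone, camera adjusted p = 0.00383, adjusted p = 0.729 with an estimated correlation). PCF11, a transcription termination factor, rose by 3.76 ± 0.36, and CDKN1A, a p53 target, by 1.35 ± 0.25. Of 230 snoRNAs and scaRNAs 4 rose, among them SNORD3C at 3.30 ± 0.49, 1 of several near-identical U3 copies, and SNORD38B at 3.30 ± 0.64 (camera adjusted p = 0.00161, adjusted p = 0.793 with an estimated correlation). Their levels were low, with SNORD3C at 5.223 CPM on GFP beads against 0.5622 CPM on uncoupled beads and SNORD38B at 2.47 against 0.2565 CPM. The mRNAs of the baits did not pass the test, with RUVBL1 at 1.08 ± 0.34 (adjusted p = 0.18), RPAP3 at 0.97 ± 0.43 (adjusted p = 0.43) and RUVBL2 at 0.19 ± 0.25 (adjusted p = 0.83). The 149 calls became 59 and 88 without replicates 1 and 2 of the GFP beads and 43 without replicate 2 of the uncoupled beads. DESeq2 called 367, and EFTUD2 (adjusted p = 0.048) lay at the threshold.

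RPAP3 recovered many of these mRNAs in untreated cells. GOLGA4 was 6.62 ± 0.23 higher on GFP beads, a 98.4-fold difference (adjusted p = 3.3e-14), POLR1A 5.85 ± 0.26, POLR2A 5.34 ± 0.20, PRPF8 5.13 ± 0.41, EP400 5.10 ± 0.26 and SRCAP 5.00 ± 0.16. EP400 stood at 1982 ± 683 CPM against 57.8 ± 4.52 CPM (SD, n = 2 each). SCAF4, a regulator of RNA polymerase II termination, was 4.61 ± 0.19 higher, POLR3A 4.09 ± 0.18 and PCF11 3.46 ± 0.15. The mRNA of RPAP3 itself (chromosome 12, 47661249 to 47706030) was 3.27 ± 0.14 higher, and those of RUVBL1 (-0.14 ± 0.16) and RUVBL2 (-0.03 ± 0.14) did not pass the test. Of 15202 genes 233 were higher and 1, NBN at -0.76 ± 0.12, was lower.

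The list of RNA polymerase subunits and assembly factors had 5 of 31 members higher with RPAP3 (5 over the list alone), POLR2B at 3.18 ± 0.14 among them, with camera adjusted p = 3.83e-21 and adjusted p = 0.0723 with an estimated correlation. INO80, SRCAP and TIP60 members rose in 4 of 29 cases (4 over the list alone), INO80 by 1.98 ± 0.13 and BRD8 by 1.62 ± 0.13 (camera adjusted p = 4.3e-15, adjusted p = 0.0969 with an estimated correlation). R2TP and prefoldin-like subunits had 2 of 11 higher (2 over the list alone), RPAP3 and URI1 at 1.69 ± 0.22, while the list's median was -0.05 (camera adjusted p = 1.24e-05, adjusted p = 0.271 with an estimated correlation). Of 16 U5 and U4/U6 proteins 3 rose, PRPF8, SNRNP200 by 0.62 ± 0.14 and EFTUD2 by 0.52 ± 0.13 (4 higher and 1 lower over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.292 with an estimated correlation). Very long cytosolic proteins had 3 of 30 higher and 11 over the list alone, MACF1 at 0.95 ± 0.15 first (camera adjusted p = 1.42e-11, adjusted p = 0.558 with an estimated correlation). Single called members of other lists were SMG1 at 0.51 ± 0.12, HSPA4 at 0.65 ± 0.15, EIF3A at 0.65 ± 0.15 and TERC, the telomerase RNA, at 1.06 ± 0.14. The 234 calls became 403 (276 higher, 127 lower) without replicate B of the GFP beads, 118 without replicate A of the uncoupled beads and 57 in a fit of all 24 libraries.

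Among 14748 genes tested in both lines, 143 were higher with RUVBL1, 233 with RPAP3 and 37 with both, where 2.26 would be shared by independent lists (odds ratio 25.6, Fisher's exact test, one-sided, p = 6.95e-35). PRPF8, EP400, SRCAP, POLR2A, POLR1A, POLR3A, POLR2B, GOLGA4, PCF11, BRD8, INO80 and SMG1 belong to those 37. Without replicate 1 of the RUVBL1 GFP beads 18 were shared, and without replicate 2 of its uncoupled beads 14. Over all 14748 genes the log2 enrichments in the lines were nearly unrelated (Pearson's r 0.0199, Spearman's rho 0.0218, across genes, which are not independent replicates). The 20 genes with the largest RPAP3 enrichment had a median of 2.63 with RUVBL1 (camera p = 0.000145 with an estimated correlation). All 233 had a median of 0.16 (camera p = 0.118 with an estimated correlation). The 17 tested of the 20 largest with RUVBL1 had a median of 3.46 with RPAP3 (camera p = 2.38e-05 with an estimated correlation). All 143 had a median of 0.04 (quartiles -0.09 to 0.59, camera p = 0.00169 with an estimated correlation).

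**Figure D1:**
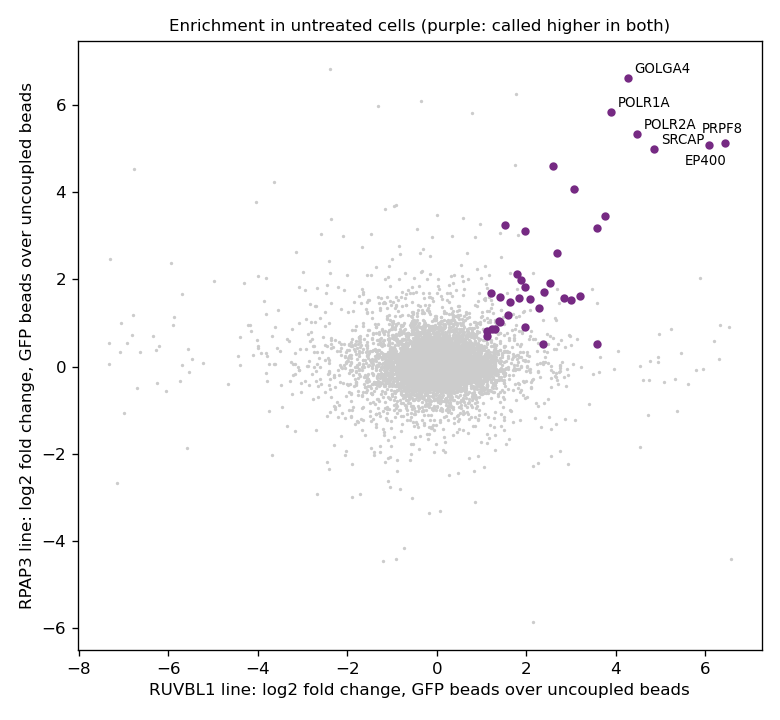
Log2 enrichment on GFP beads over uncoupled beads in untreated cells, RUVBL1 line on the x axis and RPAP3 line on the y axis, 1 point per gene tested in both lines, with the 37 genes called higher in both in purple. PRPF8, EP400, SRCAP, POLR2A, GOLGA4 and POLR1A lie at the upper right, each at 3.90 or more with RUVBL1 and 5.00 or more with RPAP3, while the 14748 genes as a whole show nearly no relation.

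The difference between the baits' enrichments in untreated cells, in a fit of all 24 libraries, was called for 68 of 16695 genes, 58 higher with RUVBL1 and 10 higher with RPAP3. CREBRF, a regulator of the CREB3 factor, differed by 2.80 ± 0.58, TRIM13, a ubiquitin ligase, by 2.62 ± 0.30 and OBI1 by 2.15 ± 0.35. SMG1 differed by 1.92 ± 0.34 and was thus recovered more with RUVBL1, as were BRD8 (1.63 ± 0.30) and CDKN1A (1.60 ± 0.31). GOLGA4 (-2.31 ± 0.44), CHERP (-2.06 ± 0.36), SCAF4 (-1.97 ± 0.43) and SCAF8 (-1.68 ± 0.37) were recovered more with RPAP3. The RPAP3 mRNA differed by -2.24 ± 0.53, which missed the threshold (adjusted p = 0.087). With upper-quartile scaling the split was 46 to 19. The count ranged from 13 to 112 when any 1 of the 8 untreated libraries was left out, being 45 and 19 without RUVBL1 GFP replicates 1 and 2, 112 and 105 without its uncoupled replicates, 13 and 40 without RPAP3 GFP replicates A and B, and 14 and 21 without its uncoupled replicates.

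Puromycin took most of the leading mRNAs off RPAP3. The change in enrichment was -5.71 ± 0.32 for POLR1A, -5.27 ± 0.25 for POLR2A, -4.96 ± 0.20 for SRCAP, -4.74 ± 0.52 for PRPF8, -4.74 ± 0.26 for GOLGA4 and -4.70 ± 0.33 for EP400. SCAF4 fell by 4.64, POLR3A by 4.08 and SCAF8 by 3.35 on that scale, and the mRNA of RPAP3 itself changed by -3.36 ± 0.19 (adjusted p = 1.3e-10). In all 37 genes fell and 1 rose, DSP, the desmosomal protein desmoplakin, by 1.61 ± 0.28. RNA polymerase subunits fell in 4 of 31 cases (5 over the list alone), POLR2B by -3.29 ± 0.19 (camera adjusted p = 4.49e-21, adjusted p = 0.0666 with an estimated correlation). INO80, SRCAP and TIP60 members fell in 4 of 29 cases (4 over the list alone), INO80 by -1.76 ± 0.19 and BRD8 by -1.28 ± 0.19 (camera adjusted p = 5.5e-18, adjusted p = 0.0666 with an estimated correlation). The R2TP list had 1 of 11 lower, RPAP3, and 2 over the list alone, with a median of 0.04 (camera adjusted p = 4.73e-05, adjusted p = 0.334 with an estimated correlation). The 17 genes selected in the RUVBL1 line for the largest enrichment had a median change of -3.32 (camera p = 1.87e-05 with an estimated correlation). All 143 genes called there had a median of -0.03 (quartiles -0.49 to 0.19), with 25 called lower and 0 higher. The 38 calls became 63 without replicate B of the untreated GFP beads and 16 in a fit of all 24 libraries.

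After puromycin 70 genes were higher on RPAP3 beads than on uncoupled beads and 0 lower in edgeR's test. The largest differences were DSP at 2.65 ± 0.21 (chromosome 6, 7541671 to 7586714), MAP1B, a microtubule-associated protein, at 1.99 ± 0.30, the proliferation marker MKI67 at 1.89 ± 0.23 and GOLGA4 at 1.88 ± 0.18, followed by GOLGB1 at 1.67 ± 0.25, MYH10 at 1.52 ± 0.15 and ATRX at 1.51 ± 0.18. Of these 70, 26 were called only after puromycin and 44 also in untreated cells, where 1.07 would be shared by independent lists (Fisher's exact test, one-sided, p = 1.63e-63). The mRNA of RPAP3 stood at -0.08 ± 0.13 (adjusted p = 1). Very long cytosolic proteins had 1 of 30 higher, MACF1 at 0.68 ± 0.15, and 12 over the list alone (camera adjusted p = 2.69e-23, adjusted p = 0.877 with an estimated correlation). EIF3A (0.83 ± 0.15) and TERC (1.28 ± 0.14) were the called members of their lists. Without GFP replicates A and B the 70 calls became 108 and 22, and without uncoupled replicates A and B 22 and 12.

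In the RUVBL1 line puromycin lowered the enrichment of 12 genes and raised that of 6. EP400 changed by -4.90 ± 0.53, PRPF8 by -4.79 ± 0.53, GOLGA4 by -4.26 ± 0.50, PCF11 by -3.90 ± 0.48, SRCAP by -3.78 ± 0.50, POLR2A by -3.39 ± 0.64 and POLR2B by -3.37 ± 0.44. BRD8 (-3.01 ± 0.35), SCAF4 (-2.45 ± 0.47) and SMG1 (-2.09 ± 0.41) fell as well. GCN1, a ribosome-bound activator of the GCN2 kinase, rose by 2.23 ± 0.42, TLN1 by 2.06 ± 0.40 and IGF2R by 1.96 ± 0.37. INO80, SRCAP and TIP60 members fell in 3 of 30 cases (3 over the list alone, camera adjusted p = 4.64e-06, adjusted p = 0.316 with an estimated correlation) and RNA polymerase subunits in 2 of 31 (4 lower and 1 higher over the list alone, camera adjusted p = 1.89e-06, adjusted p = 0.468 with an estimated correlation). Very long cytosolic proteins had 2 of 30 higher (7 over the list alone, camera adjusted p = 6.42e-10, adjusted p = 0.541 with an estimated correlation). Among genes selected in the RPAP3 line, the 20 largest had a median change of -1.78 (camera p = 0.00187 with an estimated correlation). All 233 had a median change of 0.02 (camera p = 0.549 with an estimated correlation). The 18 calls were 8 without GFP untreated replicate 1, GFP puromycin replicate 2 or uncoupled puromycin replicate 1, 9 without uncoupled puromycin replicate 2, 11 without uncoupled untreated replicate 1, and 348 (314 higher, 34 lower) without uncoupled untreated replicate 2. Total-count scaling gave 0 higher and 9 lower, and DESeq2 163 higher and 29 lower. The difference of this change between the lines was called for 0 of 16695 genes in edgeR, with 1053 at an unadjusted p under 0.05; no other tool was run on it.

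After puromycin the RUVBL1 GFP beads differed from the uncoupled beads in many more genes, 1590 higher and 611 lower. The higher ones led with TMC6 at 2.81 ± 0.30, FAN1, a DNA repair nuclease, at 2.74 ± 0.27, SNORD33 at 2.72 ± 0.60 and SNORD3C at 2.71 ± 0.46, followed by DNAH1 at 2.55 ± 0.73 and GCN1 at 2.53 ± 0.31. The snoRNAs among these were near the floor. SNORD33 stood at 1.656 CPM on GFP beads against 0.2466 CPM on uncoupled beads, and SNORD3C at 4.083 against 0.6325 CPM. The lower ones led with the non-coding RN7SK at -1.56 ± 0.42 and COX7C, a subunit of cytochrome c oxidase, at -1.56 ± 0.39, and RPL39 lay at -1.32 ± 0.35. Very long cytosolic proteins were higher on GFP beads in 10 of 30 cases (14 over the list alone), FLNA by 2.05 ± 0.37, TLN1 by 1.71 ± 0.29 and HUWE1 by 1.53 ± 0.36 (camera adjusted p = 1.67e-08, adjusted p = 0.494 with an estimated correlation). PIKK kinases and the TTT co-chaperone were higher on GFP beads in 3 of 9 (4 over the list alone), TELO2 by 1.66 ± 0.42, MTOR by 1.52 ± 0.26 and TRRAP by 1.48 ± 0.32 (camera adjusted p = 0.00243, adjusted p = 0.494 with an estimated correlation). Among U5 and U4/U6 proteins 6 of 16 were higher on GFP beads (6 over the list alone), CD2BP2 by 1.33 ± 0.22 and NCDN by 1.31 ± 0.25 (camera adjusted p = 0.00281, adjusted p = 0.494 with an estimated correlation). PRPF8 was still 1.65 ± 0.37 higher on GFP beads than on uncoupled beads, although puromycin had lowered its enrichment. EP400 at 1.17 ± 0.36, SRCAP at 1.08 ± 0.35 and INO80 at 0.86 ± 0.25 remained above beads.

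A minority of ribosomal protein and histone mRNAs were called lower on the RUVBL1 GFP beads after puromycin. Cytosolic ribosomal proteins were lower than on uncoupled beads in 13 of 85 cases and higher in 1 (33 lower and 1 higher over the list alone), with RPS21 at -1.26 ± 0.32 and RPS27L at -1.13 ± 0.27 (camera adjusted p = 4.18e-15, adjusted p = 0.494 with an estimated correlation). Replication-dependent histones were lower in 12 of 50 (17 over the list alone), with H3C2 at -1.13 ± 0.28 and H2AC4 at -1.10 ± 0.23 (camera adjusted p = 3.75e-10, adjusted p = 0.494 with an estimated correlation). CDKN1A was 1.90 ± 0.26 higher on GFP beads as 1 of 5 called p53 targets among 19 (8 over the list alone, camera adjusted p = 0.11). TSC2 was 1.32 ± 0.23 higher as 1 of 3 TSC members (camera adjusted p = 0.101), UNC45A 1.71 ± 0.25 and HYOU1 1.70 ± 0.26. VWF, 1 of 8 tested markers of blood, stromal and liver cells, was 3.09 ± 0.95 higher on 11 counts over both uncoupled libraries (list camera adjusted p = 0.81). Without 1 library the 2201 calls fell to 1356 and 343 (GFP replicates 1 and 2) or 307 and 1004 (uncoupled replicates 1 and 2), and upper-quartile scaling gave 1361 higher and 1181 lower. Of the 70 genes called with RPAP3 after puromycin, 6 were called higher here, where 7.54 would be shared by independent lists (p = 0.779, Fisher's exact test, one-sided).

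After CB-6644 RUVBL1 recovered small nucleolar and small Cajal body RNAs, the guides of rRNA and snRNA modification. SNORD15B (chromosome 11, 75404421 to 75404566) was 5.76 ± 0.41 higher on GFP beads (adjusted p = 1.1e-08), SCARNA2 (chromosome 1, 109100193 to 109100612) 4.49 ± 0.30, SCARNA7 4.06 ± 0.30 and SCARNA28 3.10 ± 0.25. The largest difference was SNORD5, at 8.92 ± 1.2. Its counts summed over both replicates were 617 on GFP beads against 2 on uncoupled beads, a scaled ratio of 441.1 with a 95% counting interval of 121.6 to 3650.3. That interval leaves out the spread between replicates, which was wide on GFP beads, at 25.45 ± 25.1 CPM (SD, n = 2). SNORD41 was 7.59 ± 0.87 higher, SNORD50A 6.98 ± 1.09 and SNORD26 6.80 ± 0.99. In all 85 of 230 snoRNAs and scaRNAs were higher on GFP beads and 0 lower in edgeR's test (115 over the list alone, camera adjusted p = 1.03e-67, adjusted p = 0.142 with an estimated correlation). Box C/D snoRNAs, which guide 2'-O-methylation, had a median of 4.75 with 75 of 134 called, and 4.65 with the 13 that had 0 bead counts set at a floor of 3 counts over the group. The 17 scaRNAs had a median of 3.10 with 10 called, and the 79 box H/ACA snoRNAs, which guide pseudouridylation, 2.14 with 0 called. The low-count filter kept genes that passed in as few as 2 libraries. Some snoRNAs may thus have been tested only because they were high on GFP beads given CB-6644. In the RPAP3 line, without CB-6644, 74 box C/D snoRNAs were tested. Class medians and called shares, here and in the later CB-6644 comparisons, could be raised by that selection. Box C/D snoRNAs made up 0.280% and 0.864% of counts in the GFP libraries against 0.0137% and 0.0125% on uncoupled beads. Box H/ACA snoRNAs made up 0.00617% in GFP replicate 1 and 0.115% in replicate 2, the library that stood apart, against 0.0123% and 0.0094% on uncoupled beads.

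**Figure D2:**
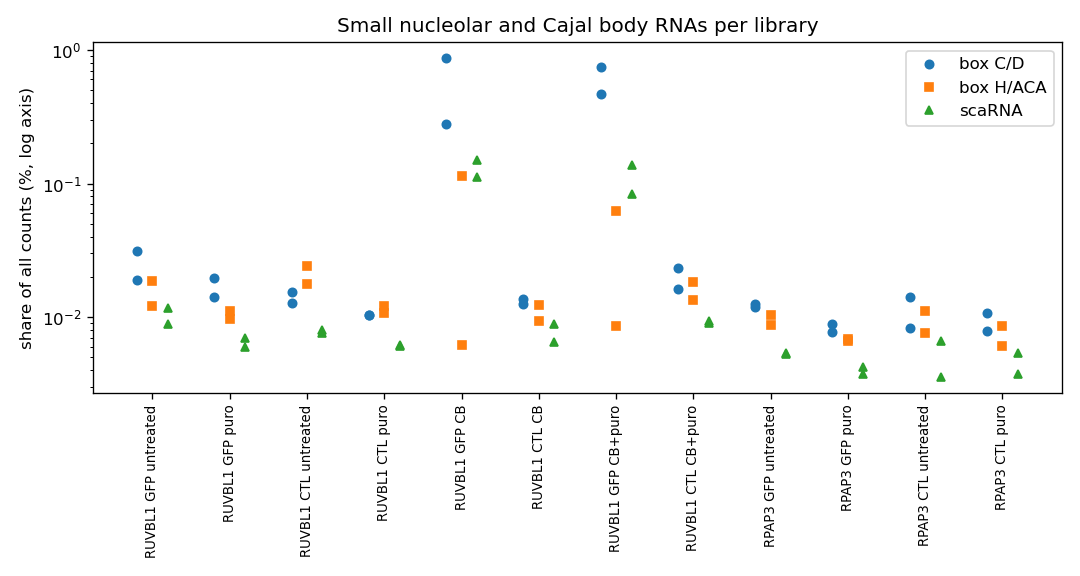
Share of all counts (percent, log axis) taken by box C/D snoRNAs, box H/ACA snoRNAs and scaRNAs in each of the 24 libraries, 1 symbol per library, grouped by line, beads and treatment. Box C/D snoRNAs reach 0.280% to 0.864% in the 4 RUVBL1 GFP libraries given CB-6644 and stay at 0.0311% or less in the other libraries, while box H/ACA snoRNAs lie high in 1 library of each CB-6644 pair.

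PRPF8 at 3.82 ± 0.40, SRCAP at 3.22 ± 0.37 and EP400 at 3.03 ± 0.38 were still recovered after CB-6644. Other mRNAs, named here outside the rule, stood higher over beads. SCAF4 lay at 2494 ± 1440 CPM on GFP beads against 46.08 ± 0.293 CPM on uncoupled beads (SD, n = 2 each). CHERP lay at 2193 ± 1070 against 100.9 ± 3.53 CPM and SCAF8 at 978 ± 563 against 46.98 ± 1.72 CPM. POLR2A at 1.51 ± 0.45 (adjusted p = 0.075), POLR1A at 1.22 ± 0.43 (adjusted p = 0.13), POLR2B at 0.81 ± 0.30 (adjusted p = 0.127), POLR3A at 0.78 ± 0.40 (adjusted p = 0.264) and EFTUD2 at 1.59 ± 0.64 (adjusted p = 0.187) did not pass the test there. INO80, SRCAP and TIP60 members were higher on GFP beads in 4 of 30 cases (7 higher and 1 lower over the list alone), with BRD8 at 1.39 ± 0.25 and DMAP1 at 1.08 ± 0.26 (camera adjusted p = 0.236). The mRNA of RPAP3 was 2.52 ± 0.45 higher on GFP beads (adjusted p = 0.014), at 239.4 ± 141 CPM against 41.7 ± 2.56 CPM on uncoupled beads (SD, n = 2 each). That of UXT, a prefoldin-like partner, was 0.99 lower. SNHG1, which hosts box C/D snoRNAs, was 1.53 ± 0.23 higher on GFP beads. RN7SK at -1.66 ± 0.42, RPPH1 at -1.60 ± 0.35, RMRP at -1.38 ± 0.33 and the near-identical RN7SL1 and RN7SL2, both at -1.36 ± 0.36, were lower. They gave 5 lower and 1 higher of 18 other structured or nuclear non-coding RNAs (6 and 2 over the list alone, camera adjusted p = 0.0398, adjusted p = 0.611 with an estimated correlation). Replication-dependent histones were lower on GFP beads in 6 of 50 cases (16 over the list alone, camera adjusted p = 1.82e-13, adjusted p = 0.533 with an estimated correlation). The split of 298 higher and 89 lower became 308 to 176 with upper-quartile scaling and 771 to 47 with total counts, which moved the median of all genes by 0.24. Without GFP replicates 1 and 2 the count was 3554 (1560 higher, 1994 lower) and 171, without uncoupled replicates 63 and 53, and without both libraries that stood apart 180 (164 higher, 16 lower), the last chosen after the data were seen.

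With CB-6644 and puromycin together 89 genes were higher and 0 lower in edgeR's test, and snoRNAs and scaRNAs made up 60 of them. SNORD68 was 7.84 ± 0.98 higher, SNORD50A 7.52 ± 1.18, SNORD3C 7.52 ± 0.51 and SNORD15B 6.31 ± 0.42, and SCARNA28 stood at 3.90 ± 0.26. Their list had 60 of 230 higher (94 over the list alone), a median of 2.58 and camera adjusted p = 5.88e-86, and it alone among all lists passed with an estimated correlation (adjusted p = 0.0466). Box C/D snoRNAs had a median of 4.13 with 52 of 134 called, or 3.94 with the 10 at 0 bead counts set at the floor, box H/ACA snoRNAs 0.73 with 0 called and scaRNAs 3.08 with 8 called. SNHG1 (1.52 ± 0.23) and CENPE, a mitotic kinesin (1.53 ± 0.24), were also higher on GFP beads. Without GFP replicate 1, the library that stood apart, the count was 56, and without uncoupled replicates 1 and 2 it was 18 and 26. Of 72 genes higher here and tested in both lines, 17 were called with RPAP3 after puromycin, where 0.342 would be shared by independent lists (p = 4.3e-25, Fisher's exact test, one-sided).

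CB-6644 changed RUVBL1 enrichment relative to untreated cells upward for 22 genes and downward for 8. SNORD17 rose by 6.50 ± 0.91, SNORD22 by 5.63 ± 0.76, SNORD27 by 5.41 ± 0.79, SCARNA17 by 4.87 ± 0.62 and SCARNA2 by 4.00 ± 0.39. The snoRNA and scaRNA list had 14 of 230 higher (68 over the list alone, camera adjusted p = 2.62e-40, adjusted p = 0.403 with an estimated correlation), with a box C/D median of 4.12. EP400 changed by -3.05 ± 0.51, POLR2B by -2.76 ± 0.43, PRPF8 by -2.63 ± 0.51, SCAMP5 by -2.1 ± 0.37 and BRD8 by -1.81 ± 0.35. Recovery did not only fall, since of the 233 genes called with RPAP3 untreated 4 rose and 4 fell, with a median change of 0.47. Markers of blood, stromal and liver cells had a median change of 2.08 over 8 tested genes, 0 of them called by edgeR (camera adjusted p = 0.0322, adjusted p = 0.467 with an estimated correlation). Total-count scaling gave 27 higher and 5 lower and moved the median of all genes by 0.26. The 30 calls became 1506 and 64 without GFP CB-6644 replicates 1 and 2 and 113 without untreated uncoupled replicate 2.

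Under CB-6644 puromycin lowered RUVBL1 enrichment of 8 genes and raised that of 0 in edgeR's test. SCAF4 changed by -5.24 ± 0.49, SCAF8 by -4.28 ± 0.44, CHERP, a splicing-related protein, by -4.09 ± 0.44, PCF11 by -3.68 ± 0.48, PRPF8 by -2.79 ± 0.51 and RPRD2 by -1.89 ± 0.35. The paralogs WASHC2C (-2.41 ± 0.35) and WASHC2A (-2.36 ± 0.36) share reads and may count as 1 signal. The mRNA of RPAP3 stood at -2.73 ± 0.61 and did not pass the test (adjusted p = 0.76). The snoRNA and scaRNA list had 0 of 230 called, a median of -0.95 and camera adjusted p = 1.87e-06 (adjusted p = 0.988 with an estimated correlation). The count was 161 and 14 without GFP CB-6644 replicates 1 and 2 and 5 without uncoupled CB-6644 replicate 2, DESeq2 gave 14, and total-count scaling moved the median of all genes by -0.20.

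**Figure D3:**
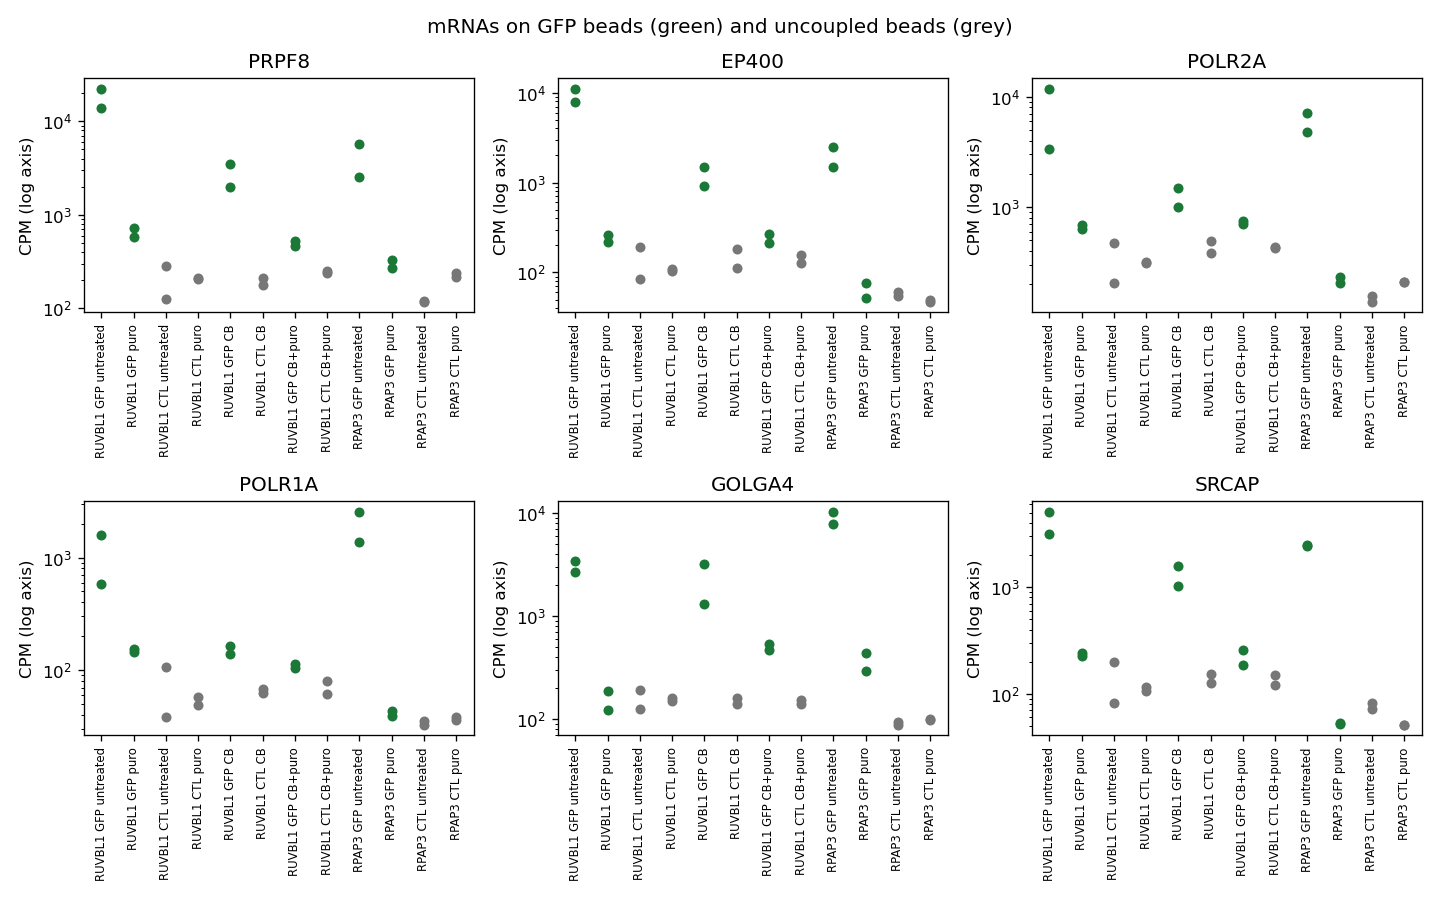
TMM-scaled CPM (log axis) of PRPF8, EP400, POLR2A, POLR1A, GOLGA4 and SRCAP in each library, 1 point per library, GFP beads in green and uncoupled beads in grey, by line, beads and treatment. Each mRNA is highest on GFP beads of untreated cells and lower after puromycin, for example GOLGA4 with RPAP3 at 366.6 ± 102 CPM after puromycin (SD, n = 2).

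Puromycin altered the RNA on uncoupled beads in the RPAP3 line, where no GFP binder was present. In that comparison 3577 genes rose and 2955 fell of 15202. The leading genes encode proteins made at the endoplasmic reticulum (ER) or lysosomal proteins, PDIA4 at 2.71 ± 0.15, HSP90B1 (chromosome 12, 103930410 to 103947926) at 2.69 ± 0.14, CTSV at 2.67 ± 0.19, PSAP at 2.61 ± 0.17 and LGALS3BP at 2.60 ± 0.14. HSP90B1 went from 185.3 ± 4.8 to 1194 ± 75.3 CPM (SD, n = 2 each). CYB5RL (-1.56 ± 0.26), BICDL1 (-1.26 ± 0.18) and the non-coding NORAD (-1.24 ± 0.15) were among the lowest. The baits' mRNAs rose by 1.14 ± 0.16 (RUVBL1), 1.02 ± 0.14 (RUVBL2) and 0.99 ± 0.13 (RPAP3).

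ER chaperones rose in 12 of 14 cases on these beads and fell in 1 (12 and 2 over the list alone), HSPA5 by 2.23 ± 0.15 and PDIA3 by 2.26 ± 0.16 (camera adjusted p = 2.38e-15, adjusted p = 0.476 with an estimated correlation). The proteasome had 26 higher and 2 lower of 31 (26 and 2 over the list alone), PSMD1 at 2.03 ± 0.13 (camera adjusted p = 9.87e-11, adjusted p = 0.476 with an estimated correlation), and HSP90 and HSP70 chaperones 13 and 1 of 20 (13 and 1), HSP90AA1 at 2.1 ± 0.16 (3.37e-07, adjusted p = 0.476 with an estimated correlation). Mitotic genes had 13 higher and 0 lower of 17 in edgeR (13 and 0), CCNB1 at 1.62 ± 0.13 (6.67e-09, adjusted p = 0.476 with an estimated correlation), and colon epithelial genes 9 and 1 of 12 (9 and 1), EPCAM at 1.99 ± 0.14 (4.82e-05, adjusted p = 0.522 with an estimated correlation). U5 and U4/U6 proteins had 10 and 1 of 16 (12 and 2), EFTUD2 at 1.52 ± 0.13 (0.000907, adjusted p = 0.476 with an estimated correlation). CCT and prefoldin had 7 and 3 of 14 (7 and 3), CCT5 at 1.93 ± 0.14 (0.00141, adjusted p = 0.621 with an estimated correlation), and ATF4 targets 6 and 1 of 16 (6 and 1), PHGDH at 1.90 ± 0.18 (0.0246, adjusted p = 0.681 with an estimated correlation). Cytosolic ribosomal proteins fell in 41 of 84 cases and rose in 1 (44 and 1 over the list alone), RPS27L by -0.80 ± 0.13 (camera adjusted p = 2.15e-06, adjusted p = 0.681 with an estimated correlation), and histones fell in 30 of 45 and rose in 0 (31 and 0), H4C3 by -0.77 ± 0.14 (5.24e-07, adjusted p = 0.636 with an estimated correlation). Other structured non-coding RNAs had 9 lower and 1 higher of 18 (0.00379, adjusted p = 0.636 with an estimated correlation) and snoRNAs 6 lower and 1 higher of 154 (0.0306, adjusted p = 0.859 with an estimated correlation).

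Lists that did not pass camera on these beads were eIF3 with 5 higher and 0 lower of 12 (adjusted p = 0.0714), snoRNP proteins with 6 and 3 of 13 (0.326), DKC1 at 1.42 ± 0.14, p53 targets with 6 and 4 of 19 (0.532), GDF15 at 2.01 ± 0.13, and INO80, SRCAP and TIP60 members with 12 and 7 of 29 (0.532). Further ones were PIKK kinases with 3 and 1 of 9 (0.639), R2TP subunits with 4 and 4 of 11 (0.851), RNA polymerase subunits with 12 and 11 of 31 (0.851), immediate early genes with 5 and 0 of 24 (0.851), very long cytosolic proteins with 3 and 2 of 30 (0.851) and the TSC complex with 1 and 0 of 3 (0.98). The median and the camera direction differed in sign for RNA polymerase subunits, immediate early genes, R2TP subunits and the TSC complex. The 6532 calls ranged from 4831 to 5318 with any library left out, and upper-quartile scaling gave 2862 higher and 4310 lower, moving the median of all genes by -0.17.

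On uncoupled beads of the RUVBL1 line edgeR called 0 genes for puromycin (1464 at an unadjusted p under 0.05) and 0 for CB-6644 (860 at an unadjusted p under 0.05). DESeq2 called 34 and 5, limma-voom 0 for CB-6644, and an unfiltered edgeR fit 74 and 17. ER chaperones had a median of 0.52 after puromycin, with 0 of 14 called over all genes and 3 over the list alone (camera adjusted p = 9.06e-06, adjusted p = 0.722 with an estimated correlation). The proteasome had a median of 0.33 with 0 of 31 called (camera adjusted p = 9.06e-06, adjusted p = 0.924 with an estimated correlation), and markers of blood, stromal and liver cells -1.21 with 0 of 8 called (0.0454, adjusted p = 0.722 with an estimated correlation). After CB-6644 the snoRNA and scaRNA list had a median of -0.49 with 0 of 230 called over all genes (1 higher and 1 lower over the list alone, camera adjusted p = 0.0395, adjusted p = 0.955 with an estimated correlation). Without untreated replicate 1 the counts were 16 for puromycin and 2 for CB-6644.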

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

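Several differences between the lines drew attention because each was tested in one fit of all 24 libraries and was called at an adjusted p under 0.05; of the explanation tests in this part, those of an unfolded protein response and of one line's preparation, and all tests on full lists, were chosen after the result was seen. In untreated cells 68 genes differed between the RUVBL1 and RPAP3 enrichments, 22 of them among the 57 named genes tested. Of these 22, those recovered more with RUVBL1 were CREBRF (2.80), TRIM13 (2.62), OBI1 (2.15), MDGA1 (1.94), SMG1 (1.92), SCAMP5 (1.88), SYT17 (1.83), TMC6 (1.83), TMEM250 (1.82), FAN1 (1.82), BRD8 (1.63) and CDKN1A (1.60). Those recovered more with RPAP3 were GOLGA4 (-2.31), CHERP (-2.06), SCAF4 (-1.97), NIN (-1.69), SCAF8 (-1.68), MIA3 (-1.52), BDP1 (-1.51), KTN1 (-1.44), BAZ2B (-1.41) and ITSN2 (-1.33). The baits were tagged in different lines, so an effect of the bait and an effect of the line cannot be told from each other.

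After puromycin 743 genes differed between the lines' enrichments, 664 higher with RUVBL1 and 79 lower, and 30 of the 60 named genes tested were among them. The higher ones of these 30 were SNORD33 (4.78, below 5 CPM in both RUVBL1 groups), FAN1 (2.99), TMC6 (2.68), C1orf226 (2.34), GCN1 (2.28), ARAP3 (2.12), INTS1 (2.1), CDKN1A (1.86), FLNA (1.83), HYOU1 (1.71), UNC45A (1.69), NCDN (1.58), CD2BP2 (1.37), TRRAP (1.34), TLN1 (1.34), MTOR (1.32) and TSC2 (1.16). The lower ones of them were DSP (-1.86), GOLGA4 (-1.84), GOLGB1 (-1.56), MAP1B (-1.50), ANAPC10 (-1.44), CRIPT (-1.44), ATRX (-1.40), RPS21 (-1.39), GPR160 (-1.36), H3C2 (-1.32), PIN4 (-1.29), H2AC4 (-1.18) and RPS27L (-1.10). Under CB-6644 the puromycin change in RUVBL1 enrichment differed from that without CB-6644 for 1 gene, CHERP, by -3.91.

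The puromycin change on uncoupled beads differed between the lines for 527 genes, 446 of them lower and 81 higher in the RUVBL1 line, and 23 of the 45 named genes tested were among them. The lower ones of these 23 were HSPA5 (-2.24), GAA (-1.98), PSAP (-1.95), LGALS3BP (-1.95), GDF15 (-1.90), HSP90AA1 (-1.90), TPP1 (-1.81), SUSD2 (-1.80), CDH1 (-1.75), HSP90B1 (-1.71), CCNB1 (-1.71), PSMD1 (-1.65), SLC3A2 (-1.64), PDIA3 (-1.61), RPN2 (-1.58), STIP1 (-1.47), PHGDH (-1.40), PSMC2 (-1.28), PDIA4 (-1.23), EPCAM (-1.18) and CCT2 (-1.17). The higher ones of them were H4C3 (1.29) and BICDL1 (1.24).

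The rise of HSPA5, PSAP and other mRNAs translated at the ER on uncoupled beads was weighed with lists chosen after it was seen and stripped of genes already seen, and was broad, with medians of 0.98 for 52 lysosomal and cell surface genes, 0.82 for the proteasome and 1.02 for 47 mitochondrial matrix genes, most of them not targets of an unfolded protein response. Such a response might add to it for ER mRNAs, but the 52 genes' margin over the proteasome list was 0.16 (bootstrap interval -0.14 to 0.61), and 0.38 (-0.09 to 0.78) for the full list of 59, which leaves that open. A cause in one line's preparation could also act, though in the RUVBL1 line, for both drugs against CB-6644, the 52 genes had a median change of 0.41 (quartiles 0.17 to 0.61) against 0.00 for all genes, and Spearman's rho between these bead changes was 0.478 across 14748 genes. The margin over the proteasome there was 0.18 (-0.02 to 0.31), or 0.22 (0.04 to 0.36) for the full list, short of the bound of 0.3, which leaves it open. EdgeR called 0 genes in that bead comparison. For puromycin alone on RUVBL1 uncoupled beads, rho with the RPAP3 bead change was lower, 0.333. The full list then had a median of 0.17, with 0 of 59 called. Release of ER-bound ribosomes, the explanation first held, needed a margin over 1 above the matrix genes, whose proteins are made in the cytosol, and a margin within 0.5 spoke against it by a bound written before the test; the values were -0.05 (-0.30 to 0.34), and 0.17 (-0.21 to 0.48) for the full lists.

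For mRNAs such as DSP and GOLGA4 that lay above uncoupled beads after puromycin with RPAP3, 2 explanations were weighed. Incomplete action of puromycin may leave some chains in place, and 44 of the 70 genes were called in untreated cells, but bait-independent recovery would share calls as well. Incomplete action does not account for DSP, whose enrichment rose with puromycin by 1.61 ± 0.28, and the 70 genes had medians of 0.73 untreated and 0.89 after puromycin. Of them 50 lay higher after it, a count raised by their selection after puromycin, and 4 had a called change, so this explanation stays open for the others. Recovery independent of the bait could appear with RUVBL1 too, where the 70 genes had a median of 0.17 after puromycin (quartiles 0.05 to 0.45), and of 0.99 after CB-6644 and puromycin, where 17 were called, but of -0.19 (-0.39 to 0.05) untreated against 0.73 with RPAP3, which leaves it open. The RUVBL1 GFP libraries after puromycin differed in sign for these genes, with medians over the mean of the RUVBL1 uncoupled beads of 0.393 in replicate 1 and -0.096 in replicate 2.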

How the results depend on the processing

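The calls of most enrichments moved with settings, while leading genes such as PRPF8 in untreated cells and SNORD15B after CB-6644 kept their direction. Over 41 settings, 4795 of 5552 values of named genes that were called at the outset kept their call, 757 lost it and 0 reversed. Of 933 values not called at the outset, 61 gained a call and 872 stayed uncalled. EFTUD2 in untreated cells, URI1, DSP in the RPAP3 puromycin change and PRPF8 in changes of enrichment lost their calls in some settings. With 2 libraries per group each count rests on few degrees of freedom. The settings chosen at the outset called 149, 2201, 387 and 89 genes for RUVBL1 untreated, after puromycin, CB-6644 and both, 234 and 70 for RPAP3 untreated and after puromycin, 18, 30 and 8 for the RUVBL1 puromycin change, CB-6644 change and puromycin change under CB-6644, 38 for the RPAP3 change, 68 between baits, 0 on RUVBL1 uncoupled beads and 6532 on those of RPAP3.

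Total-count scaling gave 818 calls for the RUVBL1 CB-6644 enrichment, 9 for the puromycin change with RUVBL1 and 152 for RPAP3 untreated. DESeq2 gave 367 for RUVBL1 untreated, 1426 after CB-6644, 208 after both drugs, 192, 174 and 14 for the puromycin change, the CB-6644 change and the puromycin change under CB-6644, 5 and 34 for RUVBL1 uncoupled beads after CB-6644 and puromycin, 108 for RPAP3 after puromycin and 208 between the baits. Limma-voom gave 180 after CB-6644 and 10 for the RUVBL1 puromycin change. Without a low-count filter the counts were 317 (RUVBL1 untreated), 1464 (CB-6644), 223 (both drugs), 199, 284 and 16 for the same 3 changes, 17 and 74 on RUVBL1 uncoupled beads, 136 (RPAP3 puromycin), 64 (RPAP3 puromycin change) and 146 (between baits). Replicate numbers were not taken to pair samples, since residuals of same-numbered libraries correlated over 0.1 in only 4 of 28 pairs of RUVBL1 groups (-0.412 to 0.27) and 2 of 6 of RPAP3 groups (-0.117 to 0.159). A shared source is not ruled out, since immediate early genes lay higher in B than in A in all 4 RPAP3 groups (for example 7.24 and 6.68 on untreated GFP beads). As a replicate block over a line the number gave 36 for the puromycin change, 53 for the CB-6644 change and 110 between baits, and for RPAP3 277 untreated, 104 after puromycin, 55 for the puromycin change and 6804 for the puromycin change in RPAP3 control beads, that is, uncoupled ones. As a block within a treatment it gave 243 untreated, 899 after CB-6644, 146 after both drugs, 45 and 67 for the puromycin and CB-6644 changes, 105 between baits, and for RPAP3 257 untreated, 96 after puromycin and 56 for the change.

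At an adjusted p under 0.01 the counts were 66, 926, 90 and 52 for RUVBL1 untreated, after puromycin, CB-6644 and both, 149 and 46 for RPAP3 untreated and after puromycin, 8 for the RUVBL1 puromycin change and 20 between baits. A log2 change over 1 left 1091 for the RUVBL1 puromycin enrichment, 77 and 26 for RPAP3 untreated and after puromycin and 1621 on RPAP3 uncoupled beads. Fits of only the libraries compared gave 70, 4805, 12 and 333 for the 4 RUVBL1 enrichments, 152 for RPAP3 untreated, 43, 11 and 4 for the RUVBL1 changes and 9 between baits. A fit of all 24 libraries gave 408, 1533 and 166 for RUVBL1 untreated, after CB-6644 and after both drugs, 57 and 16 for RPAP3 untreated and after puromycin, 135, 112 and 13 for the RUVBL1 changes, 16 for the RPAP3 change, 23 on RUVBL1 uncoupled beads after puromycin and 4056 on those of RPAP3. GFP libraries compared directly gave 805, 174, 15 and 6027 for the 3 RUVBL1 changes and the RPAP3 change. Without the 2 libraries that stood apart, a choice made after the data were seen, the counts were 180 after CB-6644, 63 for its change and 13 for the puromycin change under it.

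Under total counts the median of genes called with RPAP3 untreated, RUVBL1 CB-6644 enrichment, was 1.00 against 0.71. The median of genes called with RPAP3 untreated, puromycin change in RUVBL1 enrichment, was -0.0784 when selected at 0.01, -0.0273 for the 200 largest and -0.0732 under total counts, against 0.02. With RUVBL1 as the selecting line, the median of genes called with RUVBL1 untreated, RPAP3 untreated enrichment, was 0.14 (selection at 0.01) and -0.0412 (total counts), against 0.04. After puromycin the median of genes called with RUVBL1 untreated, RPAP3 puromycin enrichment, was 0.0766, 0.0514 and 0.0298 (selection at 0.01, 200 largest, total counts), against 0.06. For the drug's effect the median of genes called with RUVBL1 untreated, puromycin change in RPAP3 enrichment, was 0.0193 under total counts, against -0.03.

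With each library left out the counts ranged over 43 to 193 (RUVBL1 untreated), 307 to 1356 (puromycin), 53 to 3554 (CB-6644), 18 to 67 (both), 118 to 403 (RPAP3 untreated), 12 to 108 (RPAP3 puromycin), 8 to 348 (RUVBL1 puromycin change), 20 to 1506 (CB-6644 change), 5 to 161 (puromycin change under CB-6644), 31 to 63 (RPAP3 change), 13 to 112 (between baits), 0 to 2 and 0 to 16 (RUVBL1 uncoupled beads after CB-6644 and puromycin) and 4831 to 5318 (RPAP3 uncoupled beads). The genes shared by the baits ranged from 14 to 48. Medians of RPAP3-called genes with RUVBL1 ranged from -0.0201 to 0.53 untreated, 0.12 to 0.37 after puromycin, 0.52 to 0.85 after CB-6644 and 0.47 to 0.70 after both, and for the puromycin, CB-6644 and under-CB-6644 changes from -0.28 to 0.24, 0.14 to 0.68 and -0.22 to 0.10. Those of RUVBL1-called genes with RPAP3 ranged from 0.01 to 0.07 untreated, 0.0479 to 0.10 after puromycin and -0.0617 to 0.0144 for the change.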

Other observations

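Among the genes shared by the baits in untreated cells were 3 Argonaute mRNAs and that of TEP1, a telomerase-associated protein; these genes, and the tests of carry-over, lysate level and persistence without translation used further on, were chosen after the result was seen. Argonautes load small RNAs with the help of HSP90, a partner of R2TP. AGO3 was 2.53 ± 0.38 higher with RUVBL1 and 1.93 ± 0.17 with RPAP3, AGO1 2.29 ± 0.28 and 1.34 ± 0.25, and AGO4 1.59 ± 0.28 and 1.18 ± 0.19. AGO2 passed with RPAP3 at 0.60 ± 0.13 and missed the threshold with RUVBL1 at 1.10 ± 0.28 (adjusted p = 0.0559). TEP1 was 2.68 ± 0.50 higher with RUVBL1 and 2.60 ± 0.24 with RPAP3. Puromycin lowered the RPAP3 enrichment of AGO3 by -2.03 ± 0.24 and of TEP1 by -2.72 ± 0.34, while the changes of AGO1 (-1.30 ± 0.35, adjusted p = 0.854) and AGO4 (-1.09 ± 0.27, adjusted p = 0.238) did not pass the test. With RUVBL1 the changes of AGO3 (-2.65 ± 0.52, adjusted p = 0.0667) and TEP1 (-0.98 ± 0.67, adjusted p = 0.671) did not pass either. PDCD11 (2.39 and 1.72), TOPBP1 (2.07 and 1.56) and GTF3C1 (1.96 and 1.83) were further shared mRNAs, higher with RUVBL1 and RPAP3 in that order.

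Why box C/D snoRNAs such as SNORD15B came down with RUVBL1 after CB-6644 was weighed against 4 explanations. Carry-over of small structured RNAs could raise every class, but box C/D exceeded box H/ACA snoRNAs by 2.61 (bootstrap interval 2.22 to 3.06 from 2000 resamples). A set of 5 other small RNAs had a median of -1.38, the value of RMRP. RN7SK, RPPH1, RMRP, RN7SL1 and RN7SL2 had already been seen to be lower in this comparison, so that median was not an independent test. The bootstrap interval covers neither the spread between the GFP libraries nor the selection of snoRNAs by the low-count filter. In replicate 1 box C/D snoRNAs made up 0.280% of counts and box H/ACA snoRNAs 0.00617%, under both uncoupled libraries, which argues against carry-over there. In replicate 2, the library that stood apart, box H/ACA snoRNAs rose to 0.115%, so carry-over stays open for it. More snoRNA in the lysate might also raise box C/D recovery. On uncoupled beads box C/D snoRNAs changed by a median of -0.48 (quartiles -1.39 to 0.25), against 3.50 on GFP beads. SNORD15B itself lay 1.82 ± 0.37 higher on uncoupled beads after CB-6644 (adjusted p = 0.5), on top of which its GFP enrichment of 5.76 stood. No library here was of the lysate itself, and uncoupled beads hold only RNA that sticks to them. The lysate level was therefore not measured and is not excluded as a cause. Unspliced host transcripts, for which a bound was written before the test, had a median of -0.27 over 44 genes spanning called box C/D snoRNAs. Of these 44 genes 1 was called higher, and the host SNHG1 was 1.53 ± 0.23 higher on GFP beads than on uncoupled beads. Counts per gene do not separate unspliced from spliced transcripts, so this test cannot exclude unspliced hosts. After both drugs box C/D snoRNAs were still enriched, with a median of 4.13 and 52 of 134 called. Puromycin under CB-6644 changed their enrichment by a median of -0.95 (quartiles -2.02 to -0.03), with 0 of 134 called. A loss in part was thus neither shown nor excluded. The hypothesis that box C/D particles may be held on RUVBL1 without translation remained open to that extent.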
